A study of Mus musculus with 2 samples.

How the data were processed

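Single cells of the dentate gyrus of C57BL/6 mice were profiled in 2 libraries, 1 labelled young (3 months) and 1 labelled old (16 months). Per the labels' protocols, the tissue was microdissected and dissociated with papain, live cells were sorted by exclusion of propidium iodide, and libraries were made with 10x Genomics 3' chemistry, which counts the 3' ends of transcripts with unique molecular identifiers (UMIs). Cell Ranger 5.0.0 and the mm10 genome build are named per the submitters' processing notes. The number of animals behind each library, the gene annotation and the settings of the cell filter are not given in the sources used here. Because each age has 1 library, no test, p-value or standard error was computed between ages.

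The deposited table held both libraries, with cells in rows, the library in the cell name and 17592 gene columns. Its values, as deposited, were the natural log of 1 plus UMIs per 10,000 of the cell's total, and every cell summed to 10000 once the log was undone. This unit was read from the values, since the labels do not name it. Dividing each cell's linear values by the value of 1 UMI gave whole numbers, within a tolerance of 0.01, for 100% of values. These recovered UMIs were used for all sums. The design written for this work had allowed for both cases. As the values stand, no cell had under 600 detected genes and none had 15% or more of its UMIs from the 13 mitochondrial genes. Both properties were measured and are not a stated filter. Of the 17592 genes, 30 had no UMI.

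All 3893 cells were kept. The young library held 2463 cells and 16217559 UMIs, and the old library 1430 cells and 7451506 UMIs. Scanpy 1.11.5 in Python 3.11.15 was used for 2000 variable genes, 30 principal components, 15 nearest neighbours and Leiden clustering (igraph 0.11.9) at resolution 1, on both libraries together without integration. The other packages were numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Clusters were called after a class, as "-like", from 210 markers of 23 classes. A marker counted when 25% of the cluster's cells had a UMI and its level was at least 4 times that of the other cells, and 3 markers were needed. A shallow cluster with no marker among its 10 leading genes, or a cluster whose leading genes held more markers of another class, stayed unnamed. Scrublet called 37 young cells (1.50%) and 23 old cells (1.61%) as doublets. They were kept, and their removal was an alternative.

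Several choices were made only after the data were seen. Clusters whose median mitochondrial share was below 1% in both libraries were not named after a class and are called the low-mitochondrial clusters. The remaining cells are called brain-class cells here. Leading genes for naming were ranked with a pseudocount of 1. With the pseudocount of 0.1 that is used for ratios, the main astrocyte-like cluster (280 young and 285 old cells) had 0 of its markers among its leading genes and would have stayed unnamed. Sub-clusters were made of the neuroblast-like and unnamed clusters. The comparison of cells by barcode, the simulation and thinning of low-mitochondrial pairs, the set of ribosomal pseudogenes and the test on foreign marker sets were also added after the data were seen. An earlier set of 3 hand-picked ribosomal copies gave a smaller ratio than the pseudogene set. The test on foreign marker sets other than erythroid replaced a test on detection of hemoglobin genes, Ttr, S100a8 and S100a9 and a test on erythroid markers, because these hold the genes that prompted the question.

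Barcodes of 16 bases were matched between the libraries. For each pair, the gene counts of both libraries were compared with independent draws from their shared profile, over genes with at least 5 UMIs. The resulting spread is a variance that equals 1 for independent draws. On 200 simulated cells it was 0.998 for separate draws and 0.0506 for the same molecules with some lost. For the low-mitochondrial pairs, separate draws and random subsets were simulated at their real depths, and the young cells were thinned in 20 draws and compared with the lowest gene number of the old library. The interval of the area under the curve is from 1000 bootstrap draws. Pairs of different cells of 1 cluster served as the reference. To find genes with a near-identical or overlapping gene, the last 500 bases of each gene's transcripts were compared over all genes by 31-mers. The GENCODE M21 annotation of GRCm38 was used. A gene counted as sharing its 3' end when at least 50% of its 31-mers occurred in another gene. Copies and overlapping genes are not told apart by this. Of the gene columns, 17403 (98.9%) matched that annotation by name. On simulated sequences, 100% of 80 planted copies and none of 40 single genes passed the limit. Coordinates are from that annotation, on GRCm38, the assembly also called mm10.

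Shares of cells have exact (Clopper-Pearson) 95% intervals. Expression in a class was the summed UMIs per 10,000 of the class total, for classes with at least 50 cells in each library. The log2 ratio of old to young used a pseudocount of 0.1 and understates the ratio of genes near 0. Ratios of counts have exact conditional binomial 95% intervals. All intervals cover counting error only, and they assume separately drawn molecules, which the brain-class cells did not hold. A count of 0 was given a floor of 3 UMIs or cells. Simulated counts for the real genes, with 200 genes changed in each class, were run before the real counts. Unchanged genes at least 2-fold apart made up 0% in microglia-like cells (7150 genes run), 0.0396% in astrocyte-like (5248), 1.03% in endothelial-like (5529), 6.54% in pericyte-like (6006), 0.372% in mature oligodendrocyte-like (7462) and 2.07% in neuroblast-like cells (8915). Genes changed 3-fold were recovered in 82.4%, 94.3%, 86.6%, 78.4%, 72.1% and 77.2% of cases in the same order.

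The cell markers, 26 gene lists, the rule for named genes and 22 planned choices or alternatives were fixed before the data were examined. A list was described by the median log2 ratio of its members detected in at least 5% of a class's cells, with at least 4 such members, and by the percentile of that median among 10000 random lists matched on mean expression. The percentile describes these libraries and is not a test. Named genes were those detected in at least 10% of a class's cells in either library, without ribosomal, mitochondrial, hemoglobin, Gm and Rik genes and the fixed markers of other classes. The 8 with the largest positive and the 8 with the largest negative log2 ratio were taken per class, and up to 5 of each are printed. For each list described, the 2 to 4 members with the largest size of log2 ratio were taken, as were 7 genes of the neurogenic lineage. Some of the genes taken by these rules are not reported here. The gene Xist was not analysed here. Alternatives covered clustering, naming, filters, thinning to 1000 UMIs per cell, scaling, pseudocount, doublets and denominators.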

Results

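Gene expression was measured in single cells of the dentate gyrus, the hippocampal region in which new granule neurons form in adult mice. The labels set a young library, from mice of 3 months, against an old library, from mice of 16 months, with 1 library at each age. The young library held 2463 cells with 16217559 UMIs, a median of 6663 UMIs and 1803 detected genes per cell, and a median mitochondrial share of 0.158%. The old library held 1430 cells with 7451506 UMIs, medians of 3856 UMIs and 1771.5 genes, and a mitochondrial share of 6.01%. No difference between the libraries has a replicate check, and intervals are 95% and cover counting error only.

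The 2 libraries held the same brain cells. Of the 1430 barcodes of the old library, 1401 (98.0%, 97.1 to 98.6) were also in the young library, and 92.2% of these fell in the same cluster in both. When barcodes were shuffled 1000 times, the mean was 13.9% and the highest value 16.3%. The 1401 barcodes include 288 of the low-mitochondrial clusters, some of which changed cluster. In the young library 71 of these lay in low-mitochondrial cluster 0, where the old library had 27 cells. Microglia, astrocytes, vascular cells, oligodendrocytes and immature neurons were nearly all matched: 1113 of 1148 young and 1141 old brain-class cells had a partner, so that 1176 distinct barcodes remained. Within these pairs the old library had 1.12 times the UMIs of the young library for the same barcode (5th to 95th percentile 1.09 to 1.15). The spread between the paired gene counts had a median of 0.153 (0.118 to 0.316), where separate draws from the same profile give 1, and it lay below 1 in 99.9% of pairs. Pairs of different cells of 1 cluster had a spread of 2.32.

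**Figure D1:**
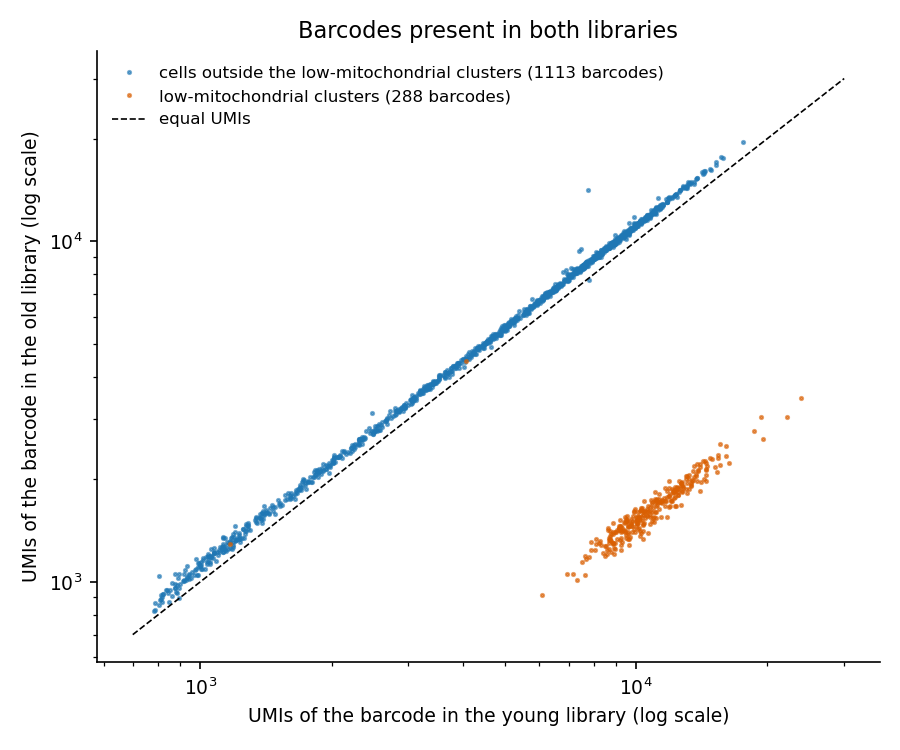
UMIs per barcode in the young library (x axis, log scale) against the old library (y axis, log scale), 1 point per barcode present in both, with the dashed line at equal UMIs. The 1113 barcodes outside the low-mitochondrial clusters lie in a narrow band at a median ratio of 1.12, and most of the 288 barcodes in the low-mitochondrial clusters lie in another band at a median ratio of 0.151.

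The brain-class cells of both libraries thus differed by less than the sampling noise and were counted as 1 sample of cells. The comparisons of age that follow are values of 2 tables of these cells, and neither a difference nor a likeness of the ages can rest on them. The 35 brain-class cells found only in the young library and the 28 found only in the old library all lay near the edges of the deposited range. Of the 35, 25 had over 12% mitochondrial UMIs, 10 had over 4200 genes and 5 had under 750 genes, and all 28 had under 750 genes. These limits were set after the data were seen, and matched cells beyond the same limits were not counted.

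Every class of brain cell took a larger share of the old library, because a set of cells with almost no mitochondrial transcripts was smaller there. Microglia-like cells, the resident immune cells of the brain, made up 15.7% of young cells (14.3 to 17.2) and 26.7% of old cells (24.4 to 29.1). Astrocyte-like cells made up 12.3% (11.1 to 13.7) and 21.7% (19.6 to 24.0), endothelial-like cells 5.36% (4.50 to 6.32) and 9.23% (7.78 to 10.9), and pericyte-like cells 2.84% (2.22 to 3.58) and 4.76% (3.71 to 5.99). Mature oligodendrocyte-like cells made up 3.33% (2.66 to 4.12) and 5.66% (4.52 to 6.99). The low-mitochondrial clusters held 1315 young cells (53.4%, 51.4 to 55.4) and 289 old cells (20.2%, 18.2 to 22.4).

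Among brain-class cells alone the shares were close, as nearly all of these barcodes were in both libraries. Microglia-like cells were 33.7% (31 to 36.5) and 33.5% (30.7 to 36.3), astrocyte-like cells 26.5% (23.9 to 29.1) and 27.3% (24.7 to 29.9), endothelial-like cells 11.5% and 11.6%, pericyte-like cells 6.10% and 5.96%, and mature oligodendrocyte-like cells 7.14% and 7.10%. The smaller classes were oligodendrocyte precursor-like (42 and 37 cells), smooth muscle-like (14 and 15), perivascular macrophage-like (10 and 11) and B cell-like (5 and 5). An unnamed cluster of 44 and 43 cells included 8 and 8 T or NK cell-like cells. A sub-cluster of 9 and 9 of its cells had 7 of 8 choroid plexus markers but stayed unnamed, since its leading genes held more erythroid markers. No cluster was named for mature granule neurons or for stem or progenitor cells. The sort for live cells and the dissociation can set which cells were sampled, and these classes were named again here from markers.

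**Figure D2:**
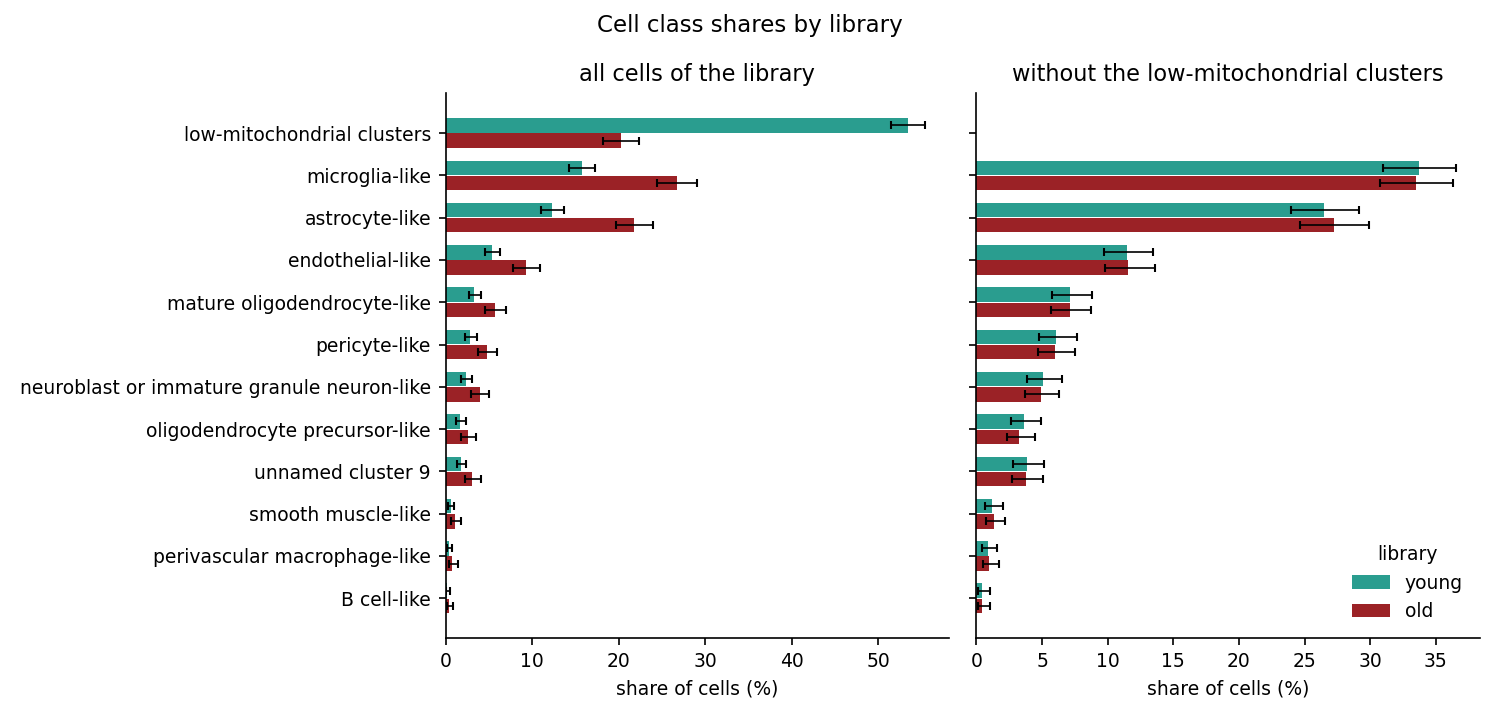
Share of cells in each class (x axis, percent; y axis, class) in the young and the old library, of all cells at the left and of cells outside the low-mitochondrial clusters at the right. Bars are shares and lines are exact 95% binomial intervals: microglia-like cells stand at 15.7% and 26.7% of all cells, and at 33.7% and 33.5% of cells outside the low-mitochondrial clusters.

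The neurogenic lineage, the question that the tissue and the ages raise, took similar shares of both libraries once the low-mitochondrial clusters were set aside. This likeness follows from the shared barcodes, 55 of which were neuroblast or immature granule neuron-like in both libraries. It says nothing about age. Neuroblast or immature granule neuron-like cells, here called neuroblast-like, were 58 of 1148 brain-class cells (5.05%, 3.86 to 6.48) in the young and 56 of 1141 (4.91%, 3.73 to 6.33) in the old library. A sub-cluster of 10 young and 10 old cells among them was Cajal-Retzius-like, with Reln, Ndnf and Trp73 among its leading genes, so these shares overstate the lineage. Of all cells the class made up 2.35% (1.79 to 3.03) and 3.92% (2.97 to 5.06). At least 1 UMI of Dcx, a microtubule-associated protein of migrating young neurons (chromosome X, 143855842 to 143933311, GRCm38), was found in 57 young (4.97%, 3.78 to 6.39) and 57 old brain-class cells (5.0%, 3.81 to 6.42). Of neuroblast-like cells 65.5% and 67.9% had a Dcx UMI, against 0.258% and 0.524% of microglia-like cells, which should lack it. Median depths were 8473.5 and 7766 UMIs in neuroblast-like cells and 7819 and 8772.5 in microglia-like cells. Of all cells, 16.0% of young and 4.83% of old cells had a Dcx UMI, since 25.6% of young and 4.15% of old low-mitochondrial cells did.

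The transcription factors of the lineage were likewise close. Within neuroblast-like cells Eomes, a factor of intermediate progenitors, was found in 50.0% of young and 48.2% of old cells, Neurod1, which drives neuronal differentiation, in 67.2% and 69.6%, and Sox11 in 84.5% and 82.1%. The shares in microglia-like cells were 0.258% and 0 of 382 for Eomes (allowing up to 0.785%), 0.517% and 1.31% for Neurod1 and 1.81% and 4.19% for Sox11. The proliferation gene Mki67 was found in 12 and 20 brain-class cells (1.05% and 1.75%), against 0 of 387 and 0 of 382 microglia-like cells (allowing up to 0.775% and 0.785%). Of the brain-class cells with Mki67, 7 and 8 were neuroblast-like (15 and 15 UMIs), and 1 and 5 were mature oligodendrocyte-like. Top2a was found in 7 and 5 brain-class cells (0.610% and 0.438%), of which 3 and 2 were neuroblast-like (5.17% and 3.57% of that class, with 29 and 14 UMIs), against 0.517% and 0.262% of microglia-like cells (2 and 1 UMIs). With each cell thinned to 1000 UMIs, which left out 58 young and 50 old brain-class cells, Dcx was found in 2.20% and 1.74%.

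Within each class the transcriptomes of the 2 libraries were close, and the genes that differed were few and mostly higher in the old library. In microglia-like cells 17 of 6938 genes were at least 2-fold apart, 16 of them higher in the old library. The counts were 11 of 4976 (10 higher) in astrocyte-like, 12 of 5271 (11) in endothelial-like, 20 of 5587 (15) in pericyte-like, 25 of 7207 (24) in mature oligodendrocyte-like and 42 of 8369 (36) in neuroblast-like cells. The SD of the log2 ratio over genes was 0.13, 0.15, 0.16, 0.23, 0.17 and 0.22 in the same order. Simulated separate draws without any change gave 0.14, 0.24, 0.34, 0.52, 0.31 and 0.41.

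Rankings by log2 ratio below are among the genes that the rule for named genes keeps, and with its pseudocount. In microglia-like cells the largest log2 ratios belonged to Rnaset2a and Rnaset2b, near-identical copies of the gene for the lysosomal ribonuclease T2. Ratios of counts were larger for some genes with few UMIs, such as Ptcra (8.36-fold) and Gal3st4 (7.23-fold). Rnaset2a (chromosome 17, 8115445 to 8148097) had 359 young and 1717 old UMIs, a log2 ratio of 2.04 and a 4.36-fold ratio of counts (3.89 to 4.90), and Rnaset2b (chromosome 17, 6970634 to 7011299) a log2 ratio of 2.01. The sulfotransferase gene Gal3st4 was at 1.58, Gng10, a G-protein gamma subunit, at 1.44, and Ptgds, a prostaglandin D synthase abundant in oligodendrocytes, at 1.33. Lower in the old library were the N-myristoyltransferase gene Nmt1 at -0.45, the Notch target Hes1 at -0.42 and the dynein gene Dync1i2 at -0.35. At least 50% of the 3' end of Rnaset2a (86.3%), Rnaset2b (74.3%) and Gng10 (96.8%) occurs in another gene, so their counts are uncertain.

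The same ribonuclease copies had the largest log2 ratios among these genes in astrocyte-, endothelial- and pericyte-like cells. In astrocyte-like cells Rnaset2a was at 1.90 and Rnaset2b at 1.76, followed by Isoc2a at 1.38, the phosphohistidine phosphatase gene Phpt1 at 1.01 and Fam228b at 0.78. Slc35f6 at -0.51, Hes1 at -0.48 and the pseudokinase gene Trib2 at -0.46 were lower. In endothelial-like cells Rnaset2a was at 2.31, Rnaset2b at 2.03 and Slc7a5, the large neutral amino acid transporter of the blood-brain barrier, at 1.22 with 98 young and 261 old UMIs (2.39-fold, 1.89 to 3.05). Nmt1 at -0.89, Vps72 at -0.53 and the transcription factor gene Mecom at -0.52 were lower. The counting intervals of Slc35f6 and Vps72 included no difference.

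In pericyte-like cells Rnaset2a was at 2.69 and Rnaset2b at 2.15, and the co-chaperone gene Dnaja4 had 1 young and 8 old UMIs, a 7.72-fold ratio of counts (1.03 to 343). The GABA-B receptor auxiliary subunit gene Kctd12 at -1.36, the neogenin gene Neo1 at -1.28 (8 and 2 UMIs, ratio of counts 0.241, 0.025 to 1.21) and the stress-induced factor Atf3 at -1.25 were lower. Over the 67 barcodes in this class in both libraries, Kctd12 was at 0.11 and Atf3 at 0.35, so their lower values rest on the few cells present in this class in the young library alone. Neo1 was at -1.04 over these barcodes, with 6 and 2 UMIs, and Dnaja4 had 1 and 7 UMIs, with intervals that included no difference for both.

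In mature oligodendrocyte-like cells the largest log2 ratios among the genes kept by the naming rule belonged to complement genes, which microglia make. The complement gene C1qc had 1 young and 33 old UMIs (29.9-fold, 5.01 to 1216), C1qb had 6 and 54 UMIs and was found in 7.32% and 56.8% of cells, and Samhd1, a dNTP hydrolase, was at 1.73. The chromatin remodelling gene Brd9 at -0.61, Eml6 at -0.52 and the endocytosis gene Necap1 at -0.44 were lower, the last 2 with intervals that included no difference. In neuroblast-like cells C1qb had 2 and 38 UMIs (18.9-fold, 4.88 to 162), and the arrestin gene Sag was at 2.12. The microglial receptor gene Trem2 had 0 and 17 UMIs, with the lower end of its interval at 4.10-fold higher in the old library. The cell cycle genes Cks2 at -1.59 and Tpx2 at -1.51 and the histone gene Hist1h2ap at -1.49 were lower, and over the 55 barcodes in this class in both libraries they were at -0.11, 0.04 and 0.21.

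Gene lists moved most where they name transcripts of other cells. Hemoglobin genes were higher in the old library in all 6 classes, with medians from 1.93 in pericyte-like to 2.37 in astrocyte-like cells, all at the 100th percentile of random lists. Hbb-bs, a beta globin of red blood cells, had 98 young and 1092 old UMIs in microglia-like cells, a log2 ratio of 3.00, and 16 and 232 UMIs in mature oligodendrocyte-like cells, a log2 ratio of 3.22. The myelin list, genes of the oligodendrocyte sheath, was at 0.52 in microglia-like (9 of 9 members higher), 0.40 in astrocyte-like (11 of 11), 0.29 in endothelial-like, 0.40 in pericyte-like and 0.62 in neuroblast-like cells (8 of 8), against -0.03 in mature oligodendrocyte-like cells (3 of 14 higher). In microglia-like cells the myelin basic protein gene Mbp was at 0.62.

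Microglial transcripts showed the same arrangement. The complement list was at 2.03 in mature oligodendrocyte-like, 1.97 in neuroblast-like, 0.48 in astrocyte-like and 0.21 in endothelial-like cells, and at -0.03 in microglia-like cells, which make most of it. The homeostatic microglia list was at 1.16 in neuroblast-like cells, with the receptor gene Csf1r at 1.83 (1 and 15 UMIs, log2 interval of the ratio of counts 1.2 to 9.29), at 0.74 in mature oligodendrocyte-like cells and at 0.24 in astrocyte-like cells, against -0.03 in microglia-like cells. In pericyte-like cells both lists were lower in the old library, at -0.30 for complement and -0.52 for homeostatic microglia, and at 0.19 and 0.13 over barcodes in this class in both libraries. The astrocyte homeostasis list was at 0.34 in microglia-like (14 of 14 higher, Clu at 0.61), 0.35 in mature oligodendrocyte-like, 0.13 in neuroblast-like, 0.10 in endothelial-like and 0.045 in pericyte-like cells (-0.002 over shared barcodes), and at -0.02 in astrocyte-like cells.

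The lists for cell division and new neurons differed by under 0.1 over the same barcodes in neuroblast-like cells. The proliferation list was at -0.55 in neuroblast-like cells, with 0 of 19 members higher and the mitotic genes Ube2c at -1.35 (12 and 2 UMIs, log2 interval of the ratio of counts -5.80 to -0.43) and Birc5 at -1.32, but at 0.06 over barcodes in this class in both libraries. It was at 0.14 in astrocyte-like cells. The adult neurogenesis list was at -0.01 in neuroblast-like cells (43rd percentile, 9 of 20 higher; -0.06 over shared barcodes), with Hopx, a stem cell factor, at -1.14 but at 0.045 over shared barcodes (12 and 14 UMIs). The list was at 0.16 in microglia-like cells. Immediate early genes, which tissue dissociation induces, were at 0.58 in mature oligodendrocyte-like (15 of 16 higher, Junb at 1.51) and 0.23 in astrocyte-like cells. They were at -0.03 in microglia-like cells, and at -0.22 in pericyte-like cells, where the value over shared barcodes was 0.03. Junb was also among the leading genes of the microglia-like cluster, and the source of the higher values was not tested.

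Housekeeping lists had medians under 0.1 in size, yet 11 of their 18 list and class pairs lay above the middle 95% of random lists. Cytosolic ribosomal proteins lay between -0.03 in neuroblast-like and 0.06 in astrocyte-like cells, mitochondrially encoded genes between -0.04 in pericyte-like and 0.08 in microglia-like cells, and nuclear genes of the respiratory chain between -0.01 in neuroblast-like and 0.09 in pericyte-like cells. Respiratory chain genes in microglia-like cells (60 of 82 higher) and ribosomal proteins in astrocyte-like cells (73 of 80) were at the 100th percentile. The other 15 lists gave 76 list and class pairs with medians from -0.19 to 0.56, of which 63 lay within 0.1. Over all lists, 58 of 142 pairs lay outside the middle 95% of random lists, where 7.10 are given by chance, and 98 of the 142 medians were under 0.1 in size.

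Over the 1113 barcodes of brain-class cells present in both libraries, the log2 ratio of 8195 genes had an SD of 0.10, and 98.0% of genes lay within 0.2. Pearson's r of log levels across genes, which are not independent replicates, was 0.997. Only 14 genes were at least 2-fold apart. The 12 higher in the old library were Gng10 at 2.24, Rnaset2a at 2.14, Rnaset2b at 2.13, Hba-a1 at 1.35, Wdr74 at 1.30, Hba-a2 at 1.29, Phpt1 at 1.17, Slc7a5 at 1.15, Hbb-bs at 1.11, Adap2os at 1.07, Gm11808 at 1.03 and Hbb-bt at 1.01. Gm10076 at -2.03 and Gm10073 at -1.14 were lower. These genes are named by this limit, after their values were seen. At least 50% of the 3' end occurs in another gene for 11 of the 14. Hbb-bs was found in 20.7% of these cells in the young and 82.7% in the old library.

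**Figure D3:**
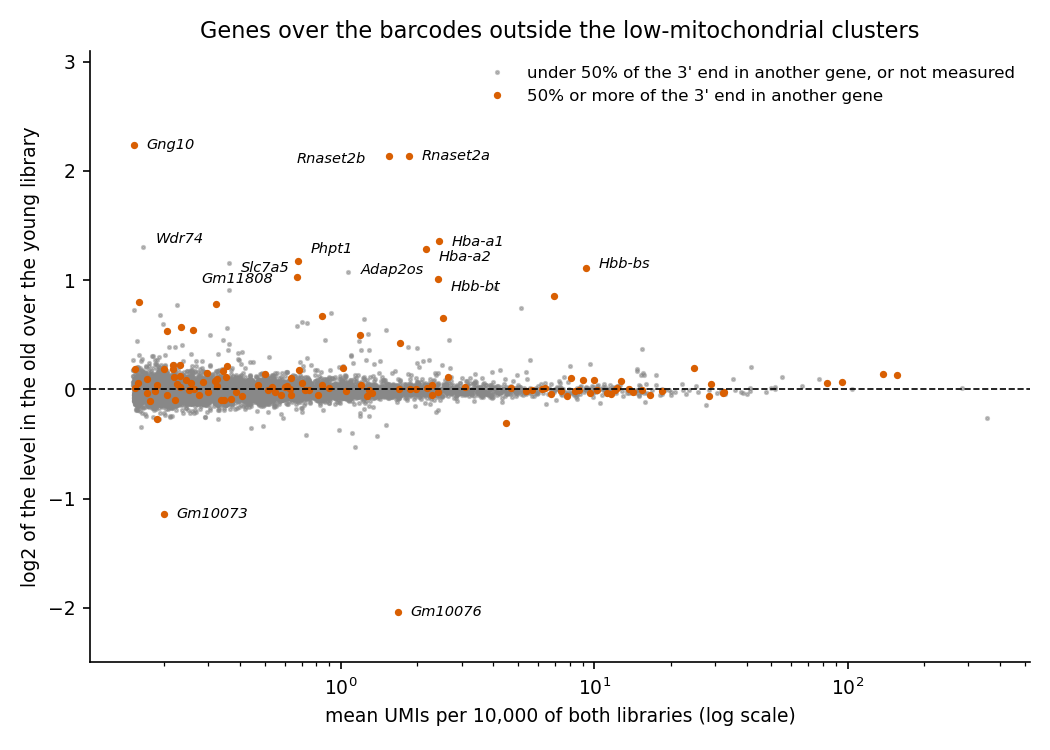
Log2 ratio of old to young level (y axis) against the mean level in UMIs per 10,000 (x axis, log scale), 1 point per gene over the 1113 shared barcodes outside the low-mitochondrial clusters, with genes that share at least 50% of their 3' end in orange. The 14 labelled genes are at least 2-fold apart, from Gm10076 at -2.03 to Gng10 at 2.24, and 98.0% of all 8195 genes lie within 0.2.

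Fixed marker sets were summed over the same barcodes. Sets of other classes are called foreign here, although a class may also express some of them. Erythroid markers were higher in the old library by a ratio of 9.60 (8.17 to 11.3) in microglia-like, 7.71 (6.21 to 9.66) in astrocyte-like, 6.26 (4.55 to 8.80) in endothelial-like, 10.7 (7.38 to 15.9) in mature oligodendrocyte-like and 7.02 (4.90 to 10.3) in neuroblast-like cells. Mature oligodendrocyte markers had ratios of 1.66 in microglia-like and 1.70 in neuroblast-like cells, microglia markers 2.65 in mature oligodendrocyte-like and 1.23 in astrocyte-like cells, and endothelial markers 2.03 in microglia-like cells. A class's own markers had ratios from 0.959 to 0.999. Of 55 foreign sets with at least 200 UMIs, 38 were higher in the old library, 20 with an interval above 1, and 0 had an interval below 1.

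**Figure D4:**
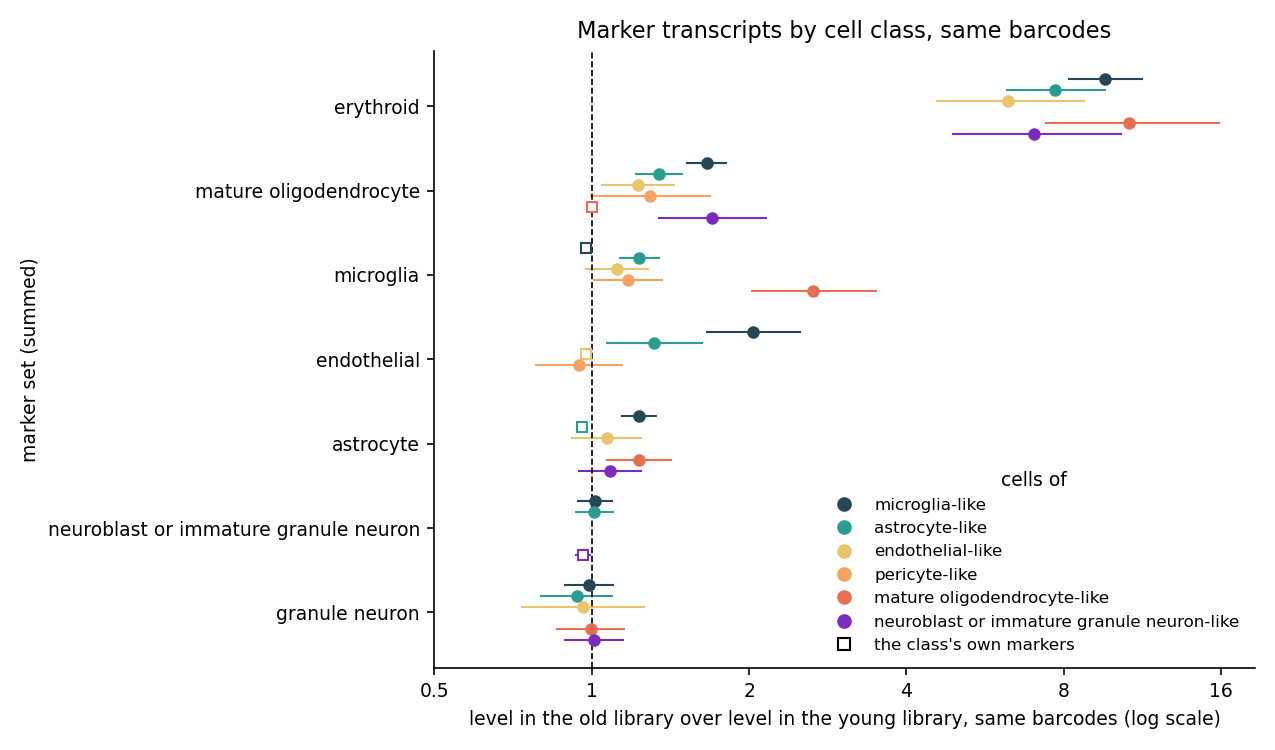
Ratio of old to young level (x axis, log scale) of summed marker sets (y axis) in the cells of each class over the same barcodes, with exact 95% conditional binomial intervals as lines and the class's own markers as open squares. Erythroid markers lie between 6.26 and 10.7, and the own markers between 0.959 and 0.999.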

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

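All tests weighed in this part were chosen only after the result was seen. Cells with almost no mitochondrial transcripts were outside the comparison of classes, and there is no control library. They made up 53.4% of the young library and 20.2% of the old library, above the shares of 0.122% and 0.210% that a count of 0 allows. Their median mitochondrial share was 0.0814% in the young and 0.574% in the old library, against 6.90% and 7.37% in brain-class cells.

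For these cells, nuclei of mouse cells are argued against by Malat1, a nuclear RNA, whose level was 8.43 and 12.7 UMIs per 10,000 against 386 and 323 in brain-class cells, a ratio of at most 0.0393. Mouse cells of another tissue or stage were not decided by the 288 shared barcodes. In these the young library had 6.61 times the total UMIs but 10.2 against 11.5 mitochondrial UMIs per cell, a ratio of ratios of 0.135. Mitochondrial UMIs of a cell should follow its total, but a loss that differs by gene between the libraries could also give this ratio. Cells of another organism, with reads of conserved genes placed on the mouse genome, stay open and are a candidate explanation: ribosomal pseudogenes had 3.66 and 3.02 UMIs per 100 ribosomal protein UMIs against 0.0563 and 0.0484 in brain-class cells, a ratio of at least 62.4. No reads were analysed here, so the organism was not tested. A difference of age would give each library its own cells, and it is argued against as the explanation of the unequal shares: 99.7% of the old low-mitochondrial barcodes (98.1 to 100.0) were in the young library. Lower depth in the old library, which puts the shallower cells below the lowest gene number kept, stays open as a candidate explanation. With young cells thinned to 0.151 of their UMIs, 80.8% of the 338 left with at least 600 genes had a partner, against 1.54% of the 977 others, and gene number ranked cells with a partner above the rest with an area under the curve of 0.985 (0.976 to 0.992).

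The brain cells shared by the libraries have 2 explanations that the pairs argue against. Different cells that share a barcode by chance would differ as other cells of 1 cluster do, and the spread of pairs was 0.0658 of that. Separate draws of molecules from the same cells would give a spread near 1, and the median was 0.153. What remains may be the same molecules counted in 2 runs of processing or a table filled from the same cells under both names, which these values do not separate. Age does not explain the pairs or their differences, since both names hold the same cells. What age does to this tissue was not tested, since no second set of brain cells was analysed here.

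Genes that differed within the same cells have 2 technical explanations that stay open, and both may act, but they are not shown to cover every gene. Reads shared with a near-identical or overlapping gene, assigned differently in the 2 libraries, fit an over-representation of 32.9 (22.3 to 43.3). This interval counts genes as independent, although they include copies of each other, such as Rnaset2a and Rnaset2b, that were seen before the test. Of 39 genes at least 0.5 apart on the log2 scale, 20 (51.3%, 34.8 to 67.6) shared their 3' end, against 1.56% of all genes. RNA of other cells that was lost or removed in the young library was not decided. There were 50 marker sets of other classes, without the erythroid set that holds the hemoglobin genes in question. Their median young to old ratio was 0.961 (quartiles 0.824 to 1.01). This median cannot size a loss, because some of these sets were high in the class itself. In young microglia-like cells the monocyte or dendritic cell set was at 493 UMIs per 10,000, against 306 for the class's own markers. Of the 50 sets, 15 were higher in the old library with an interval above 1, and 0 had an interval below 1. The hemoglobin genes are also among those that share their 3' ends. Age as their source is argued against by the same cells, since different cells at each age would give pairs a spread of 1 or more, not 0.153.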

How the results depend on the processing

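Among the values of the main comparisons under the alternatives, 63 kept their direction and size, 34 moved and 12 changed sign, and the 40 named genes kept their sign in 231 of 240 values and the described lists in 233 of 246. The alternatives restricted to brain-class cells or to barcodes in both libraries, the pseudocount of 0.1 for naming and all alternatives for the share of matched barcodes were chosen after seeing the data. The others were planned. Pairing by animal and leaving out a replicate were not possible because each age has 1 library, and pairing was by barcode only. Depth limits genes with few UMIs most, and where no cause is given, the cause was not tested.

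The ratio of old to young median UMIs, 0.579 over all cells, was 1.12, 1.06, 1.13, 1.12 and 1.10 within microglia-, astrocyte-, endothelial-, pericyte- and mature oligodendrocyte-like cells, 0.917 in neuroblast-like cells, 0.218 in the low-mitochondrial clusters and 1.10 over brain-class cells. Over the 55 neuroblast-like barcode pairs the median ratio per barcode was 1.12, with medians of 6924 young and 8029 old UMIs. The value over all cells combines the unequal shares of the clusters with the lower depth of the low-mitochondrial cells in the old library.

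Old minus young shares in percentage points were 11 for microglia-like, 9.41 for astrocyte-like, 3.87 for endothelial-like, 1.91 for pericyte-like, 2.34 for mature oligodendrocyte-like, 1.56 for neuroblast-like and -33.2 for low-mitochondrial cells. Among brain-class cells only, where the low-mitochondrial cells leave the denominator, the first 6 were -0.231, 0.776, 0.0705, -0.138, -0.0438 and -0.144. With at least 1000 genes per cell they were 22 for microglia-like, 6.61 for endothelial-like, 3.52 for pericyte-like, 4.52 for mature oligodendrocyte-like, 2.94 for neuroblast-like and -56.5 for low-mitochondrial cells. Without microglia-like cells in the denominator they were 15.0 for astrocyte-like, 6.24 for endothelial-like and 3.78 for mature oligodendrocyte-like cells. Naming each cell by its marker score gave 5.01 for astrocyte-like and -13.4 for neuroblast-like cells, a naming that also took in low-mitochondrial cells, and the pseudocount of 0.1 for naming gave 0.844 for astrocyte-like cells, because their main cluster stays unnamed. The difference in cells with a Dcx UMI, -11.2 points, was -4.11 when thinned and 0.0305 among brain-class cells. Barcodes of the old library found in the young one went from 98.0% to 96.5% with at least 1000 genes per cell.

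Genes at least 2-fold apart, in the order microglia-, astrocyte-, endothelial-, pericyte-, mature oligodendrocyte- and neuroblast-like cells, numbered 4, 2, 4, 3, 1 and 3 with a pseudocount of 1, which shrinks the ratios of low genes, and 8, 6, 63, 189, 218 and 387 in cells thinned to 1000 UMIs, which leaves fewer UMIs per gene and draws each library anew. Detection in at least 1% of cells, which adds low genes, gave 75 in pericyte-like and 75 in neuroblast-like cells. Removing doublets gave 21 in endothelial-like cells, and barcodes in the class in both libraries gave 13 in pericyte-like cells. List and class pairs outside the middle 95% of random lists went from 58 to 19 when thinned.

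Of the named genes, Kctd12 in pericyte-like cells was at 0.49 without doublets and 0.11 over shared barcodes, Atf3 there at 0.67 thinned, 0.77 without doublets and 0.35 over shared barcodes, Tpx2 in neuroblast-like cells at 0.75 thinned and 0.036 over shared barcodes, and Hist1h2ap there at 0.21 over shared barcodes. Among the list values given in the Results, complement (0.19), homeostatic microglia (0.13) and immediate early genes (0.025) in pericyte-like cells changed sign over shared barcodes. So did proliferation (0.059) in neuroblast-like cells and, from 0.045 to -0.0019, astrocyte homeostasis in pericyte-like cells. Ribosomal, mitochondrial and respiratory chain lists, all under 0.1 in size, also changed sign. With the mean over members, ribosomal proteins in microglia-like cells were at 0.028, and mitochondrially encoded genes at -0.021 in endothelial-like and -0.052 in mature oligodendrocyte-like cells. Thinned, ribosomal proteins were at 0.0058 in microglia-like and -0.019 in mature oligodendrocyte-like cells, mitochondrially encoded genes at -0.0022 in endothelial-like and -0.0051 in mature oligodendrocyte-like cells, and respiratory chain genes at -0.027 in pericyte-like and -0.029 in mature oligodendrocyte-like cells.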

Other observations

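This part reports values with no test of an explanation, and the genes and cells in it were chosen after the data were seen. Transcripts assigned to some genes of embryonic tissue were found in the low-mitochondrial clusters, and no gene list was tested there. Pax3, a transcription factor of the dorsal neural tube and neural crest, had a UMI in 67.9% of the 364 young cells of cluster 0, in 49.3% of the 436 of cluster 1, in 66.4% of the 134 of cluster 7 and in 9.77% to 39.8% of the other low-mitochondrial clusters, and in 0 of 1148 young brain-class cells, which allows up to 0.261%. Sox2, a neural progenitor factor, was found in 87.6% of cluster 0 but 12.1% of cluster 13, against 25.8% of young brain-class cells, and the intermediate filament gene Vim in 99.7% of cluster 0 against 20.6%. Neurod1 and Prrx1 were found in 1.65% and 3.85% of cluster 0, below 3.83% and 10.5% in brain-class cells. The mitotic gene Top2a was found in 97.8% of cluster 7, in 24.2% or less of the other low-mitochondrial clusters and in 0.610% of brain-class cells. In cluster 12 the mesenchymal genes Twist1 and Col1a2 were found in 96.0% and 92.9%. In cluster 13 the neuronal genes Stmn2 and Elavl2 were found in 100% and 97.1%, and the neural crest gene Tfap2b in 92.5%. Most of these genes were not particular to these clusters. Col1a2 was found in 58.8% of cluster 0, Stmn2 in at least 58.5% of each low-mitochondrial cluster, Elavl2 in 87.0% of cluster 14 and Tfap2b in 76.8% of cluster 12. Twist1 was found in 7.42% or less of the other low-mitochondrial clusters. Some of these genes helped to define the clusters. Assignment to a mouse gene is that of the deposited table.

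Within the barcodes shared by the low-mitochondrial clusters, the old library had 0.151 times the UMIs of the young library, and the spread of the paired counts was 1.05 (5th to 95th percentile 0.918 to 1.23). At these depths, simulated separate draws gave 1.00 (0.904 to 1.11) and a random subset of the same molecules 0.784 (0.682 to 0.870). A loss that differs by gene would also raise the spread of a subset, so separate draws are not shown by it. The cells found in both libraries were the deeper ones: their median in the young library was 10486 UMIs, against 6628 for the young low-mitochondrial cells without a partner. Ribosomal protein genes took 37.2% of young and 36.1% of old UMIs in these clusters, against 8.92% and 9.06% in brain-class cells.

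The Y-linked genes Ddx3y and Kdm5d had a UMI in 41.7% and 11.1% of young and in 44.8% and 11.9% of old brain-class cells. In the low-mitochondrial clusters Ddx3y was found in 17.3% and 5.54%, and Kdm5d in 0.152% and 0.346%. The choroid plexus gene Ttr had a UMI in 0.436% of young and 9.82% of old brain-class cells. Its level over these cells was 10.3 and 10.9 UMIs per 10,000. Ttr was the first leading gene of the unnamed sub-cluster of 9 young and 9 old cells with choroid plexus markers.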
